A study of Mus musculus with 8 samples.

How the data were processed

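Total RNA of 8 tumours, 1 per mouse, was labelled with Cy3 and hybridised to Agilent one-colour mouse arrays. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 9.5.3. Per the file headers, the software gave each spot a raw mean intensity, a local background intensity and a processed intensity. The processed intensity was background-subtracted and detrended within the array, with values at or below background replaced by a small positive surrogate, and was not scaled between arrays. The authors also deposited a value table of the same arrays on a log2 scale. Its columns share a median of 8.36 and the same sorted values, so it had been quantile normalized with the control spots included. Each column correlated, across spots, at 0.996 to 1.000 with the log2 raw mean intensity of its array and at 0.984 to 0.990 with the log2 processed intensity. How the authors set its offset is not given in the sources used here. That table served as an alternative only.

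Each array held 44397 spots, 43020 of them not controls, for 39429 different probes. A RefSeq accession named 26055 probes through the current mouse gene table, 8652 kept the file's gene name and 4722 had no symbol. The updated symbol differed from the file's name for 3358 probes. Probe coordinates are those of the array files, on the mm9 build.

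The 75th percentile of the processed intensity was 4706 to 5795 on slide 1 and 1587 to 2783 on slide 2. Between 46 and 85 spots were saturated on each array of slide 1 and 0 on slide 2. Well above background were 66.9% to 76.4% of the spots of an array. Signal near background and the 4 arrays per group limit the precision.

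Log2 processed intensities were scaled by subtracting each array's 75th percentile over the probes that are not controls. Spots of a probe were averaged, leaving out spots with an outlier flag. Probes were kept if they were well above background on at least 4 of the 8 arrays. That left 28340 probes, 25374 of them with a gene symbol, and 9 of these were left out because an array had only flagged spots. A gene was represented by its brightest kept probe, chosen over all arrays without regard to group; 4666 of the 19778 genes had more than 1 kept probe. Where a probe was not well above background on any array of a group, its fold is given as "at least". That bound sets the brighter group's mean against the mean, per dim array, of the higher of the probe's own value and the lowest signal well above background. For Mx1 and Serpina3g, well above background on only some AZD1480 arrays, a bound was formed likewise, raising only the dim arrays. Cfd, dim on a vehicle array as well, is given as measured.

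The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with treatment as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. A log2 difference of at least 1 was a second criterion. Means and SDs are on the log2 scale over 4 arrays per group. SEs are limma's moderated SEs of the log2 difference, with each gene's variance drawn towards that of all genes. The labels state 4 mice per group, so replicates are separate animals. In all, 39 gene lists, 19 of pathways and 20 of cell type markers, each with at least 5 measured genes, were tested with camera at its preset correlation between genes of 0.01. P-values were adjusted over the lists. Camera was repeated with an estimated correlation for each list. Other tests of the lists were fry and a two-sided exact permutation test of the mean list value over the 70 ways of drawing 4 of 8 arrays. The smallest exact p, 0.0286, can pass the adjustment over 39 lists only if most lists reach it. For each list the genes passing were also counted adjusted over the list alone.

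The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. A listed symbol that was not among the tested genes was looked up as a synonym. This wrongly put Pitx3 in place of Ptx3 in the list of NF-kB and inflammatory cytokine genes. It also put Bik in place of Blk among the B and plasma cell markers. The rule names (a) the 10 largest changes per direction among genes that pass and do not overlap between groups, or, where none passes, the 5 with the smallest p per direction as not passing, leaving out clone and model names. It also names (b) Jak1, Jak2, Stat3, Socs3, Pim1, Bcl2l1, Birc5, Ccnd1, Myc, Mmp9, Il6, Vegfa and a gene not reported here, and (c) up to 4 members with the smallest p of each list described. Here 4 were named for the 2 interferon lists and the MHC, JAK-STAT feedback and acute phase lists, and up to 2 for the others.

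The 2 slides, each scanned apart, were treated as batches and fitted as a covariate and one by one. Slide alone gave 0 genes by limma, with 2636 at an unadjusted p under 0.05. Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, the replicate number as a block, trend and robust variance, array weights, the authors' values, and leaving out each array.

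The procedure was tested on simulated data: values for the 19778 genes of this comparison, drawn with their own means and spread, with 200 genes changed, in 5 draws. Of 2-fold changes 21.8% were recovered and of 4-fold changes 53.6%, with 5 false calls per draw. A shifted list was called in 5 of 5 draws. The genes were drawn independently of each other, whereas in the data the type I interferon list had an estimated correlation of 0.61. The draws therefore do not show how camera performs on correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.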

Results

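Transcript levels were measured in ovarian tumours of female C57BL/6 mice that carry the MISIIR-TAg transgene, in which SV40 T antigen is expressed from the promoter of the Müllerian inhibiting substance type II receptor gene (Amhr2). When tumours had reached about 500 mm3, 4 mice received vehicle and 4 received AZD1480, an inhibitor of the JAK1 and JAK2 kinases, at 30 mg/kg, and tumour tissue was taken 6 h later. Each tumour was hybridised to its own one-colour array, on 2 slides that each held 2 vehicle and 2 AZD1480 arrays. Between 66.9% (AZD1480 replicate 2) and 76.4% (vehicle replicate 2) of spots were well above background, and 19778 genes were tested. The precision is limited by the 4 arrays per group. The comparison asked which transcripts differ shortly after JAK inhibition in these tumours.

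Interferon-induced genes were lower in the AZD1480 tumours. The mean log2 value of the type I interferon response list was -1.53 relative to vehicle, a 2.89-fold difference (SD 0.21 over 4 vehicle arrays and 0.99 over 4 AZD1480 arrays), and 43 of its 43 measured genes were lower. Among its named members, Ifi44 differed by a log2 difference of -3.51 ± 0.60 (limma's moderated SE, n = 4 per group, 11.4-fold). The transcript of Mx1, an interferon-induced gene, was at least 11.7-fold lower (-4.37 ± 0.56 as measured). It was well above background on 1 of the 4 AZD1480 arrays, and for this bound the others were set no lower than the lowest signal well above background on the array. Herc6, a ligase for the ubiquitin-like protein Isg15, and Trim25, a ubiquitin ligase of the antiviral RNA sensing pathway, had smaller differences (-0.66 ± 0.14 and -0.71 ± 0.16). The interferon gamma response list was at -0.79 (1.72-fold, SD 0.10 in vehicle and 0.36 in AZD1480), with 38 of 40 genes lower. Its members with the smallest p were Tgtp2, an interferon-inducible GTPase (-2.09 ± 0.28), the immunoproteasome subunits Psmb9 (-0.94 ± 0.16) and Psmb8 (-1.03 ± 0.17), and the guanylate-binding protein Gbp7 (-1.18 ± 0.21).

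By limma's camera test both lists fell relative to all other genes, type I with an adjusted p = 3.83e-42 (adjusted p = 0.257 with an estimated correlation) and interferon gamma with an adjusted p = 6.48e-28 (adjusted p = 0.131 with an estimated correlation). In both lists the means of 4 of 4 AZD1480 arrays lay below those of all vehicle arrays, which gave a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 arrays allow. Of the type I genes, 20 passed limma's test adjusted over the list alone and 0 over all genes, with 27 at an unadjusted p under 0.05. Of the interferon gamma genes, 17 passed adjusted over the list alone and 0 over all genes, with 18 at an unadjusted p under 0.05. Mx1, Ifi44, Herc6, Trim25, Tgtp2, Psmb9, Psmb8 and Gbp7 fell by the test over their own list. Within slide 1 the type I list was at -2.07 and the interferon gamma list at -1.01, and within slide 2 they were at -0.99 and -0.56. Without AZD1480 replicate 1, the array farthest from the others, they were at -1.06 and -0.62. The 2 kept probes of Tgtp2 differed (-2.09 and -1.09). Tgtp2 has a near-identical neighbour, Tgtp1, so the signal is uncertain as to which copy it comes from.

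**Figure D1:**
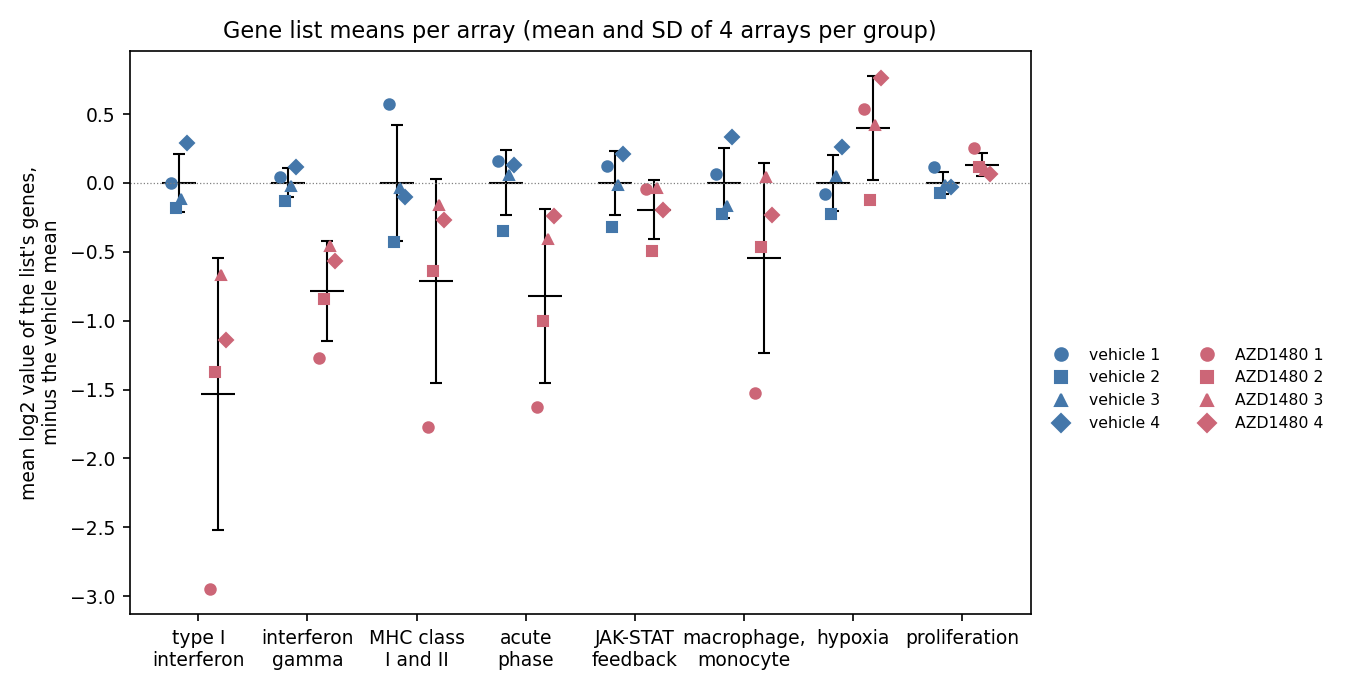
Mean log2 value of 8 gene lists on each array, minus the mean of the vehicle arrays, with symbols for the replicates and bars for the mean and SD of 4 arrays per group. All 4 AZD1480 arrays lie below all vehicle arrays in both interferon lists, at -0.67 to -2.95 in the type I list, and AZD1480 replicate 1 is lowest in 5 of the lists shown.

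Antigen presentation genes were lower along with the interferon lists, although the lists overlap. Tap1, Tap2, Tapbp and Ciita belong to the interferon gamma list as well. The list of MHC class I and II presentation genes was at -0.71 (SD 0.42 in vehicle and 0.74 in AZD1480), with 19 of 19 measured genes lower. Its members with the smallest p were the peptide transporter subunit Tap2 (-0.61 ± 0.16), the class I light chain B2m (-0.96 ± 0.33) and the class I genes H2-T23 (-1.50 ± 0.57) and H2-K1 (-1.47 ± 0.57). The list fell by camera (adjusted p = 7.26e-09; adjusted p = 0.569 with an estimated correlation). The means of 2 of 4 AZD1480 arrays lay below those of all vehicle arrays (two-sided exact permutation p = 0.143). None of its genes passed limma's test adjusted over the list alone or over all genes, and 6 had an unadjusted p under 0.05. The 6 were Tap2, B2m, H2-T23, H2-K1, H2-Q7 and H2-D1, all of the class I pathway. The class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were at -0.43 to -0.56. Other class II pathway genes ran from -0.31 (H2-Oa) to -0.96 (H2-DMb1), and the remaining class I pathway genes from -0.12 (H2-Q4) to -0.59 (Tap1). The shift of the list was -1.28 within slide 1 and -0.14 within slide 2, and -0.35 without AZD1480 replicate 1, where H2-T23 was at -0.95 and H2-K1 at -0.94.

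Markers of macrophages and monocytes were lower in the same tumours, at -0.55 (SD 0.25 in vehicle and 0.69 in AZD1480), with 17 of 20 genes lower, among them the Fc receptor Fcgr3 (-0.92 ± 0.24) and the mannose receptor Mrc1 (-1.04 ± 0.31). This list fell by camera (adjusted p = 1.62e-06; adjusted p = 0.569 with an estimated correlation), while 0 of its genes passed adjusted over the list alone or over all genes and 3 had an unadjusted p under 0.05 in limma. The shift was -0.92 within slide 1, -0.17 within slide 2 (adjusted p = 0.0556) and -0.22 without AZD1480 replicate 1.

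Among direct targets of STAT3, the transcription factor that JAK kinases activate, Cebpd was lower while the list as a whole moved little. Cebpd, itself a transcription factor gene (-1.34 ± 0.25), Socs3, the feedback inhibitor of JAK signalling (-0.84 ± 0.26), Stat3 itself (-0.90 ± 0.26) and the metalloreductase gene Steap4 (-1.98 ± 0.65) had the smallest p of the JAK-STAT feedback list. The kinase gene Pim1, another member, had a positive difference (0.67 ± 0.40). The list was at -0.19 (SD 0.23 in vehicle and 0.21 in AZD1480), with 18 of 31 genes lower and 13 higher. It fell by camera (adjusted p = 0.0323; adjusted p = 0.569 with an estimated correlation). Cebpd alone passed limma's test adjusted over the list alone, 0 genes passed over all genes, and 5 had an unadjusted p under 0.05. Its shift was -0.17 within slide 1 and -0.21 within slide 2, and its call was lost within slide 1 (adjusted p = 0.197). It was also lost without AZD1480 replicate 2 (-0.094, adjusted p = 0.365) or 4 (-0.19, adjusted p = 0.145) and without vehicle replicate 1 (-0.15, adjusted p = 0.145) or 4 (-0.12, adjusted p = 0.214). The 2 kept probes of Stat3 were at -0.90 and -0.42.

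Ccnd1, which encodes cyclin D1, was lower by a log2 difference of -1.58 ± 0.31 (2.99-fold). It was the 1 gene of the list of tumour-associated STAT3 targets that passed limma's test adjusted over the list alone. It was likewise the 1 gene to pass so in the ERK and growth factor feedback list, to which it also belongs (limma adjusted p = 0.0149 over that list). Of the tumour-associated STAT3 targets 0 passed over all genes and 3 had an unadjusted p under 0.05. In that list the matrix metalloprotease gene Mmp7 was at -1.41 ± 0.46 and Myc at -0.56 ± 0.30, whereas the angiogenic factor Vegfa was at 1.17 ± 0.59, the apoptosis inhibitors Birc5 and Bcl2l1 were at 0.26 ± 0.16 and 0.16 ± 0.19, and the mucin gene Muc1 at -0.78 ± 0.40. Mmp7 and Muc1 were each well above background on 3 of the 4 AZD1480 arrays. Over the list's 23 measured genes, 13 lower and 10 higher, the shift was -0.23 and the list was not called (camera adjusted p = 0.230). The shift was -0.11 without AZD1480 replicate 1, -0.36 without AZD1480 replicate 4, -0.41 within slide 1, -0.046 within slide 2 and -0.071 with a filter on all 8 arrays. Mmp9 and Il6 did not pass the detection filter and were not tested. The transcripts of the drug's targets had differences of 0.055 ± 0.32 (Jak1) and -0.58 ± 0.37 (Jak2). The sign for Jak1 was negative without AZD1480 replicate 1 (-0.23). Without that array Jak2 was at -0.22, Vegfa at 0.59, Myc at -0.28, Mmp7 at -0.94 and Birc5 at 0.17.

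**Figure D2:**
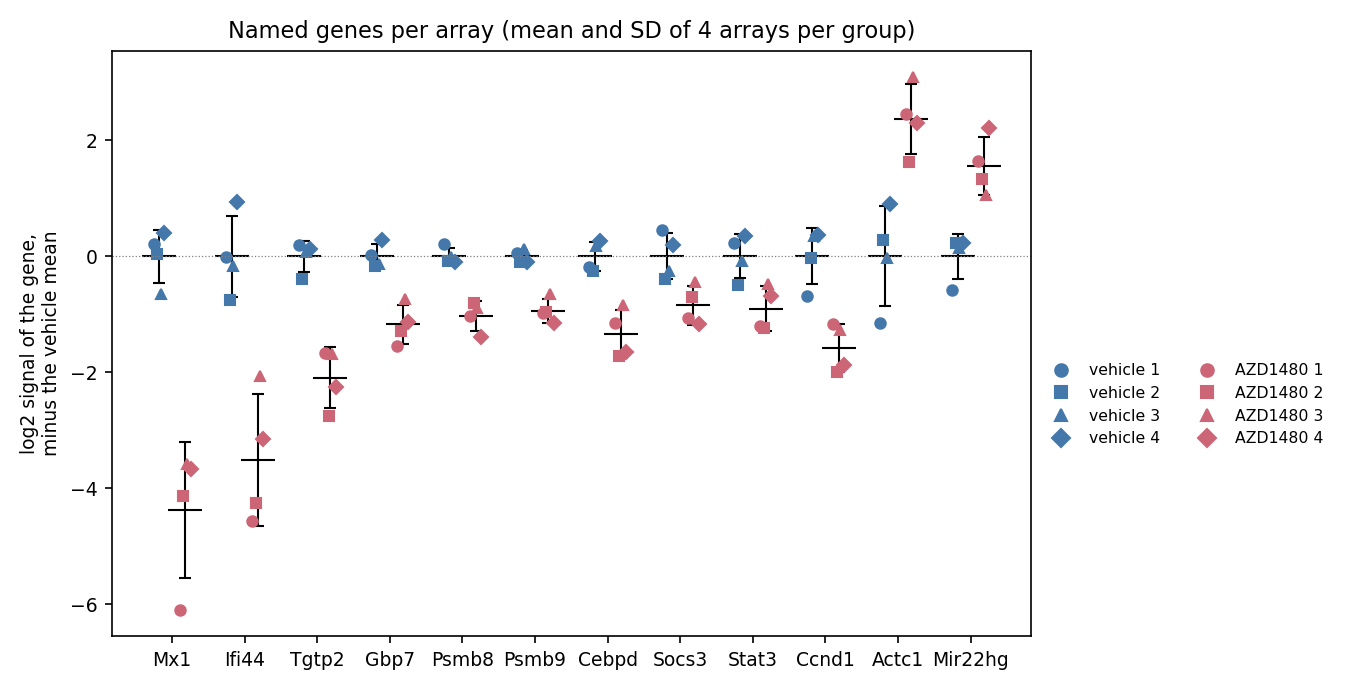
Log2 signal of 12 named genes on each array, minus the mean of the vehicle arrays, with symbols for the replicates and bars for the mean and SD of 4 arrays per group. Mx1 is plotted as measured, although 3 of its AZD1480 values were not well above background, and for Stat3 the lowest vehicle array lies just below the highest AZD1480 array.

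Acute phase genes, many of which respond to interleukin 6 and STAT3, were lower as a list, at -0.82 (SD 0.24 in vehicle and 0.63 in AZD1480), with 16 of 21 genes lower. The members with the smallest p were the siderophore-binding protein Lcn2 (-2.16 ± 0.59), Lrg1 (-1.47 ± 0.43), the serpin Serpina3g (-2.64 ± 0.84 as measured, well above background on 2 of 4 AZD1480 arrays, at least 4.50-fold) and the copper carrier ceruloplasmin, Cp (-0.69 ± 0.23). The list fell by camera (adjusted p = 2.35e-05; adjusted p = 0.257 with an estimated correlation). In limma 0 of its genes passed adjusted over the list alone or over all genes, and 7 had an unadjusted p under 0.05. The shift was -1.22 within slide 1, -0.42 within slide 2 and -0.55 without AZD1480 replicate 1, which was at -1.63. AZD1480 replicate 4, at -0.24, lay within the range of the vehicle arrays.

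The hypoxia and proliferation lists were the 2 that were higher in the AZD1480 tumours. Hypoxia-induced genes were at 0.40 (SD 0.20 in vehicle and 0.38 in AZD1480), with 26 of 31 higher, including the mitochondrial gene Higd1a (0.76 ± 0.31) and Pfkfb3, a regulator of glycolysis (1.09 ± 0.46). The list rose by camera (adjusted p = 0.000482; adjusted p = 0.569 with an estimated correlation). It was at 0.36 within slide 1 (adjusted p = 0.0696) and 0.44 within slide 2, and its call was also lost with array weights (0.18, adjusted p = 0.105). Proliferation genes were at 0.13 (SD 0.082 in vehicle and 0.084 in AZD1480), with 30 of 46 higher, including the mitotic kinase Aurka (0.51 ± 0.14) and the mitotic regulator Cdc20 (0.52 ± 0.16). That list rose by camera (adjusted p = 0.0128; adjusted p = 0.569 with an estimated correlation) and was at 0.16 within slide 1 and 0.10 within slide 2 (adjusted p = 0.193). Its call was lost without AZD1480 replicate 1 (0.092, adjusted p = 0.0910), 2 (0.14, adjusted p = 0.0546) or 3 (0.15, adjusted p = 0.116) and without vehicle replicate 2 (0.11, adjusted p = 0.148). In both lists 0 genes passed limma's test adjusted over the list alone or over all genes, against 2 hypoxia and 7 proliferation genes at an unadjusted p under 0.05.

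Markers of other cell types also fell by camera in 4 further lists, each with wide spread between tumours. Oviduct ciliated cell markers, among them the radial spoke genes Rsph4a (-1.42 ± 1.04) and Rsph1 (-1.08 ± 0.84), were at -1.69 (adjusted p = 2.35e-05; adjusted p = 0.569 with an estimated correlation). That shift came from AZD1480 replicate 1, which was at -6.63, and without it the list was at -0.048 (adjusted p = 0.381), Rsph4a at -0.24 and Rsph1 at -0.14. Epithelial tumour markers such as Wfdc2 (-1.31 ± 0.51) were at -0.61 (SD 1.01 in vehicle; adjusted p = 0.00193; adjusted p = 0.569 with an estimated correlation). They were at -0.21 without vehicle replicate 1 (adjusted p = 0.168), at -0.43 without AZD1480 replicate 2 (adjusted p = 0.0546) and at -0.97 without vehicle replicate 2. Adipocyte markers such as Fabp4 (-2.70 ± 1.24) and Cfd (-5.11 ± 2.71 as measured, well above background on 3 vehicle arrays and 1 AZD1480 array) were at -1.20 (adjusted p = 0.0128; adjusted p = 0.569 with an estimated correlation). Their call was lost without vehicle replicate 3 (-0.42, adjusted p = 0.175), AZD1480 replicate 2 (-1.08, adjusted p = 0.147) or AZD1480 replicate 4 (-1.21, adjusted p = 0.104). Endothelial markers such as Vwf (-1.12 ± 0.32) and Lyve1 (-1.17 ± 0.37) were at -0.26 (adjusted p = 0.0418; adjusted p = 0.576 with an estimated correlation). Their call was lost without vehicle replicate 4 (-0.055, adjusted p = 0.873) or without AZD1480 replicate 1 (-0.23, adjusted p = 0.0613), 2 (-0.21, adjusted p = 0.147) or 4 (-0.24, adjusted p = 0.327). In these 4 lists 0 genes passed limma's test adjusted over the list alone or over all genes. The numbers at an unadjusted p under 0.05 were 0 of the ciliated, 1 of the epithelial, 0 of the adipocyte and 2 of the endothelial markers. Within slide 1 and slide 2 the shifts were -3.16 and -0.23 for ciliated, -0.87 and -0.35 for epithelial, -0.51 and -1.90 for adipocyte, and -0.20 and -0.32 for endothelial markers. Camera no longer called the ciliated and epithelial lists within slide 2 (adjusted p = 0.461 and 0.193), nor the adipocyte and endothelial lists within slide 1 (adjusted p = 0.432 and 0.399).

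In all, camera called 12 of 39 lists, 10 lower and 2 higher, and 0 with an estimated correlation, by fry or by the exact permutation test of the array means. The exact test could call a list only if most of the 39 reached its smallest p, so its count decides little. Without AZD1480 replicate 2 camera called 7. The other 27 lists had adjusted p between 0.0726 and 0.930, among them T cells (-0.21, adjusted p = 0.179), fibroblasts and stroma (-0.43, adjusted p = 0.155; these 2 were at -0.097 and -0.13 without AZD1480 replicate 1), granulosa and luteal cells (-0.28, adjusted p = 0.453) and immediate early genes (0.0089, adjusted p = 0.693; -0.11 without AZD1480 replicate 1). The 0.0726 belongs to the list of NF-kB and inflammatory cytokine genes, which held Pitx3 in place of Ptx3. Among all 35 ways of parting the 8 arrays into 4 and 4, 16 gave as many called lists. With slide as a covariate the 12 lists were again called. Without AZD1480 replicate 1, granulosa and luteal markers were at -1.28 (adjusted p = 0.00534) and ERK and growth factor feedback genes at -0.33 (adjusted p = 0.00181, against -0.10 and adjusted p = 0.230 with all arrays), but neither was called there with an estimated correlation (adjusted p = 0.804 for both).

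No single gene passed over all 19778 genes. Limma with Benjamini-Hochberg adjustment called 0 genes (smallest adjusted p = 0.647), and 0 at least 2-fold. At an unadjusted p under 0.05 there were 340 higher and 345 lower genes, 685 in all where 988.9 were expected by chance. Of the 685, 63 were at least 2-fold higher and 210 at least 2-fold lower. The balance of directions depended on the arrays used, with 1081 higher and 540 lower without AZD1480 replicate 3 and 223 higher and 580 lower without AZD1480 replicate 4. The lower genes with the smallest p were Mx1, Tgtp2, the apolipoprotein L gene Apol10b (-2.29 ± 0.32), the monocyte chemokine Ccl12 (-2.74 ± 0.40) and the lymphocyte activation marker Cd69. Their adjusted p ran from 0.647 to 0.827. Cd69 was not well above background on the AZD1480 arrays, where it was at least 1.12-fold lower. The higher genes with the smallest p were the RNA gene Mir22hg (1.56 ± 0.30, adjusted p = 0.957), the cardiac actin gene Actc1 (2.36 ± 0.47), Troap (0.86 ± 0.18), Osgin1 (0.66 ± 0.15) and Rcor2 (0.75 ± 0.17), with adjusted p of up to 0.974. The 2 kept probes of Apol10b were at -2.29 and -0.44. The groups did not overlap in 518 genes (2.62%), where chance gives 2.86%. Without AZD1480 replicate 1 the count was again 0, and the smallest adjusted p was that of Mx1 (0.0582).

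The probes behind these values lie, on the mm9 build of the mouse genome, on chromosome 16 at 97668644 to 97668703 for Mx1, on chromosome 11 at 48871837 to 48871896 for Tgtp2, and on chromosome 17 at 34337771 to 34337830 for Psmb8 and 34319174 to 34319233 for Psmb9. Those of Cebpd (chromosome 16, 15888459 to 15888518), Socs3 (chromosome 11, 117827480 to 117827539), Stat3 (chromosome 11, 100749598 to 100749657) and Ccnd1 (chromosome 7, 152116202 to 152116261) were taken from the same annotation.

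AZD1480 replicate 1 differed from the other tumours across the transcriptome. Its correlation with the other arrays, across genes, was 0.871 to 0.904, while the other 7 arrays correlated at 0.954 to 0.988 among themselves. The first principal component held 51.3% of the variance and set this array at -193.4, against -2.99 to 48.3 for the others. Granulosa and luteal markers were highest there (2.69 relative to the vehicle mean), followed by vehicle replicate 3 (2.32) and vehicle replicate 1 (0.72). Vehicle replicates 2 and 4 were at -1.45 and -1.58, and the 3 other AZD1480 arrays were at -0.58 to -1.65.

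**Figure D3:**
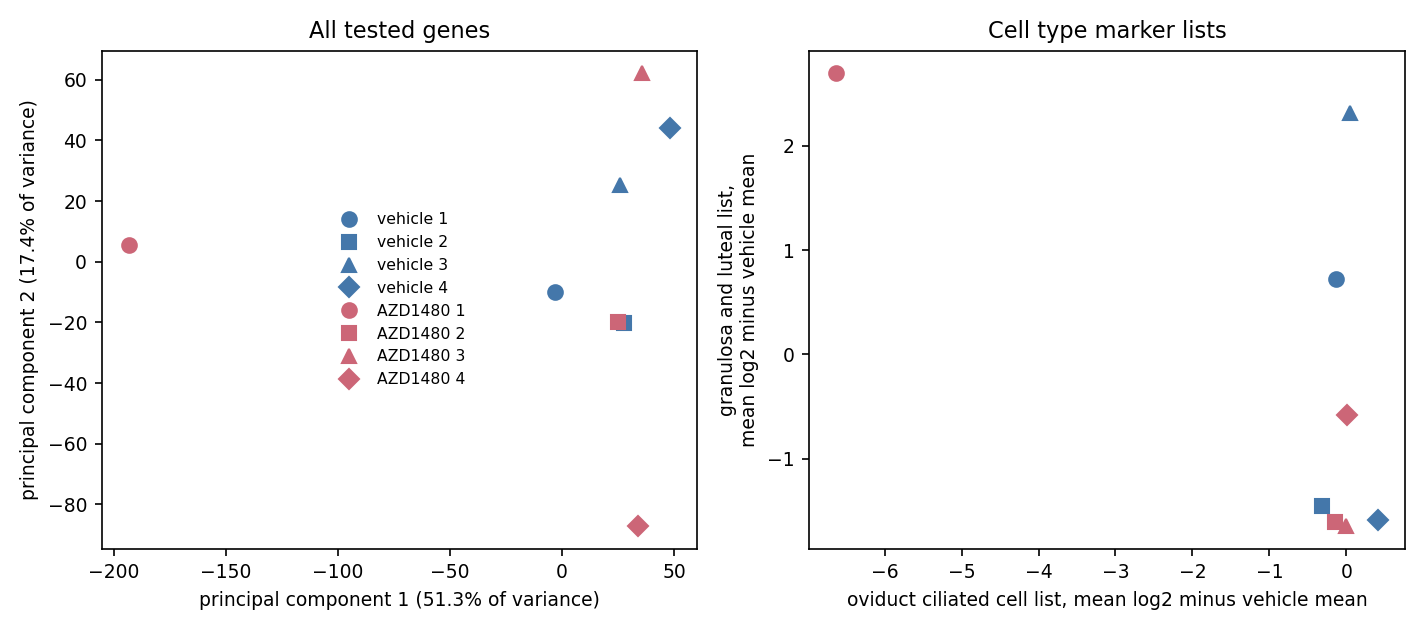
Left, the 8 arrays on the first and second principal components of all tested genes (51.3% and 17.4% of the variance). Right, the mean log2 value of the granulosa and luteal list against that of the oviduct ciliated cell list, each minus the vehicle mean; AZD1480 replicate 1 stands alone at -6.63 and 2.69.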

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

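The splits of the arrays counted for the number of called lists and for both interferon lists, and the test of array quality, were chosen before their results were seen; the counts of splits for the genes and all other tests in this part were chosen after. Among 134 sets of 4 values examined (named genes, described lists and array measures, per group), the farthest array stood apart by Dixon's ratio, the gap to its neighbour over the group's range, in 10, where chance gives about 6.7. Of the 10, 5 concern AZD1480 replicate 1. It was lowest of the AZD1480 arrays for the ciliated cell list (ratio 0.977, at -6.63 with the next at -0.14), Rsph1 (0.972), Rsph4a (0.947), Mmp7 (0.835) and the mean correlation to the other arrays (0.855). Mmp7 was well above background on only 3 of the 4 AZD1480 arrays. AZD1480 replicate 3 was highest of the AZD1480 arrays for Mrc1 (0.985) and Cfd (0.980). Vehicle replicate 3 was lowest of the vehicle arrays for Myc (0.945) and vehicle replicate 1 for Mir22hg (0.898), and vehicle replicate 4 was highest for the endothelial list (0.878).

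The first pattern is the lower level of the interferon lists in the AZD1480 tumours. Taken for each list alone, 1 of 35 splits, the real one, gave a camera p as small, which is the smallest share that 35 splits allow. The -log10 p was 43.0 for the type I list (highest other split 24.2) and 28.5 for the interferon gamma list (highest other 12.4). This share does not exclude chance, since 39 lists were tested and these had the smallest camera p of them. Nor is chance excluded once all 39 lists are counted (exact permutation of the array means, adjusted p = 0.557 for both). That test could not have excluded it, since its smallest p of 0.0286 passes the adjustment only if most lists reach it. The aberrant tumour of AZD1480 replicate 1 was not the whole source, since the other 3 AZD1480 arrays were all below vehicle (mean -1.06). Each slide held 2 vehicle and 2 AZD1480 arrays, so a slide offset falls on both groups alike by design. The type I difference held within both slides (-0.99 in the smaller case), which follows from the separation of the groups and is no separate test. The type I difference exceeded that of the macrophage markers by a mean of -0.99, with this excess lower in 4 of 4 AZD1480 arrays than in all vehicle arrays (exact permutation p = 0.0286, the smallest possible). A smaller share of macrophages does not account for all of it if such a loss lowers both lists alike, which was not tested. For the interferon gamma list the excess was -0.24 (exact permutation p = 0.257; -0.41 without AZD1480 replicate 1, with the other 3 AZD1480 arrays below all vehicle arrays), so fewer macrophages and lower expression per cell cannot be told apart there, with AZD1480 replicate 1 on the other side of zero from the rest; an effect of the inhibitor on interferon signalling is a hypothesis.

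The second pattern is the distance of AZD1480 replicate 1 from the other tumours. Poor array quality is argued against, since replicate spots of a probe had a median SD of 0.0505 there and up to 0.0582 elsewhere, and its mean spike-in correlation (0.998) lay within the range of the others. An exchange of labels with a vehicle tumour would, if AZD1480 lowers the type I list, put a vehicle array among the other 3 AZD1480 arrays on it. On that list 0 vehicle arrays were as low as any of these (vehicle minimum -0.18), and this array was at -2.95. This separation of the groups was known before the test was chosen, so it does not decide about an exchange. An exchange with a tumour outside these 8 stays open as well. An effect shared by the AZD1480 tumours is argued against as the cause: over the 746 genes in which this array was over 16-fold from the vehicle mean, its median distance from that mean was 5.20 log2 units, and that of the other 3 AZD1480 arrays in the same direction was 0.028 to 0.042, within the range of the vehicle arrays (-0.30 to 0.27). An effect of AZD1480 in this mouse alone was not tested. Another cell makeup of the piece of tissue may account for it. By the test set for this, 11 of the 16 ciliated markers were still well above background there (16 of 16 on every other array), which left it undecided. That count does not weigh against another makeup, since it does not measure how far the markers fell. The mean of the ciliated list was -6.63 there, against -0.32 to 0.41 on the other arrays.

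The third pattern is the number of calls. With 0 genes called, any split reaches the real count (35 of 35, with and without the 2-fold criterion), so these counts decide nothing about chance. One other split called 322 genes (304 at least 2-fold). For the lists, 16 of 35 splits reached the real count of 12 and the highest other split gave 19, so chance cannot be excluded for that number. The split with 322 genes and 19 lists set vehicle replicates 1, 3 and 4 and AZD1480 replicate 3 against the rest. Its 322 genes against 0 point to a structure of the samples, but the split was picked out after its counts were seen and what it reflects was not tested; the split by slide gave 0 genes and 7 lists.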

How the results depend on the processing

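All alternatives here were chosen before the data were examined. Limma called 0 genes under every one, at unadjusted p under 0.05 between 346 (within slide 2) and 1621 (without AZD1480 replicate 3), with the smallest adjusted p between 0.0582 and 1.000. Median scaling gave 259 higher and 385 lower genes at that p, and no filter on dim probes gave 495 and 351. Under all settings of camera with the preset correlation the type I list stayed lower (-0.99 to -2.07), as did the interferon gamma list (-0.56 to -1.01), and both stayed called, as did the MHC and acute phase lists. Over the 12 lists called, calls were lost in 18 of 96 values with single arrays left out and in 21 of 156 under the other such settings. Apart from the fits within a slide, the proliferation call was lost with normexp (0.13, adjusted p = 0.0721), median scaling (0.11, 0.0593), no filter on dim probes (0.13, 0.101) and the authors' values (0.10, 0.0519), and the hypoxia call with array weights (0.18, 0.105). The endothelial call was lost with quantile normalization (-0.28, 0.0818), median scaling (-0.29, 0.0593), trend and robust variance (-0.26, 0.0519) and the authors' values (-0.25, 0.0684), and the adipocyte call with the filter on all 8 arrays (-0.85, 0.0600). The exact permutation test could call a list only if most lists reached its smallest p. The number of lists called was 0 with an estimated correlation, 0 by fry and 0 by the exact permutation test, and 7 to 15 when single arrays were left out. Under those 3 tests the type I list (-1.53) had adjusted p = 0.257, 0.249 and 0.557, and the interferon gamma list (-0.79) had 0.131, 0.0573 and 0.557. The JAK-STAT feedback list (-0.19) had 0.569, 0.800 and 0.681. Its call was also lost with median scaling (-0.22, adjusted p = 0.0593), within slide 1 (-0.17, 0.197) and with the authors' values (-0.19, 0.0510), while with array weights it was kept (-0.32, 9.62e-05). Its shift ran from -0.30 to -0.094 with single arrays left out. Jak1, near 0 with all arrays, was at -0.13 within slide 2, -0.23 with array weights and -0.014 with the authors' values, and at -0.23 to 0.25 with single arrays left out. The cause of these changes was not tested.

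The arrays do not settle whether replicate numbers pair the samples. Deviations of same-numbered arrays correlated, across genes, at 0.36, 0.36, 0.13 and -0.06. Of the 8 samples, 5 correlated best with their own number among the 4 arrays of the other group. Replicates 1 and 2 of both groups lay on slide 1 and replicates 3 and 4 on slide 2, so such likeness can also come from the slide. With the replicate block limma called 0 genes (880 at an unadjusted p under 0.05) and camera 11 lists, without the JAK-STAT feedback list (-0.19, adjusted p = 0.0787). Beyond these, no named gene reversed, nor did any of the 12 called lists or the list of tumour-associated STAT3 targets; the other lists were not followed through all settings. Signal limits the dim genes: with no filter on dim probes 27224 genes were tested, again with 0 called, and the median of all genes was then 0.10 above 0.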

Other observations

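The gene families and single genes in this part, and the test of the hypothesis, were chosen after their values were seen. Among families of interferon-inducible genes, only members outside all fixed lists were counted, and no enrichment test was run. The median log2 difference of the Oas oligoadenylate synthetase genes was -0.62, with 6 of 6 such members lower, and that of the Pyhin genes of DNA sensing (Ifi20x, Ifi21x and Mndal) was -1.45 (4 of 5 lower). The Apol genes were at -0.84 (7 of 9), the Ifit genes at -2.20 (2 of 3), the Phf11 genes at -1.60 (2 of 3) and the Slfn genes at -0.17 (3 of 3). These medians were negative under every scaling and background alternative tried, but nearer 0 with normexp (Ifit -0.84, Apol -0.24, Oas -0.37, Pyhin -1.11, Phf11 -1.36, Slfn -0.051) and with the authors' values (Ifit -1.24, Apol -0.54, Oas -0.51, Pyhin -1.28, Phf11 -1.46, Slfn -0.068). Trim genes went both ways, with 22 of 42 lower and a median of -0.041, which turned to 0.020 with normexp. By limma 0 of these genes passed over all genes. The numbers lower with an unadjusted p under 0.05 were 2 Oas, 4 Pyhin, 3 Apol, 2 Ifit, 2 Phf11, 0 Slfn and 2 Trim genes.

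Some cell identity genes differed between tumours within both groups, and others did not. Amhr2, whose promoter drives the transgene, was at 6.83 in AZD1480 replicate 1 and 5.39 in vehicle replicate 1 (log2 relative to the array's 75th percentile), and at -0.75 to 1.43 in the other 6. Inha, an inhibin subunit of granulosa cells, was at 4.44 in AZD1480 replicate 1, 2.00 in vehicle replicate 1 and 1.56 in vehicle replicate 3, and below -2.7 in the rest. Nr5a1, a regulator of steroidogenesis, was at 3.70 and 1.36 in AZD1480 replicate 1 and vehicle replicate 1. Hsd3b1 and Star, also of the granulosa and luteal list, were highest in vehicle tumours. Hsd3b1 was at 3.98 in vehicle replicate 3 and 1.52 in AZD1480 replicate 1, and Star at -2.40 in vehicle replicate 1 and -2.49 in AZD1480 replicate 1. The granulosa gene Foxl2, in contrast, was at 3.53 in AZD1480 replicate 1 and 3.27 to 3.65 on the other 7 arrays, and Wt1 was at 5.20 against 4.44 to 5.15. The oviduct genes Ovgp1 and Foxj1 were at -3.52 and -2.22 in AZD1480 replicate 1, against 5.35 to 6.61 and 3.33 to 4.06 on all other arrays. Between this array and the mean of the other 7, 158 genes were over 16-fold higher and 598 over 16-fold lower.

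One hypothesis was that interferon-driven genes responded more than the STAT3-driven genes of the JAK-STAT feedback list at this time. The type I list moved by -1.34 more than the feedback list (SD 0.13 in vehicle and 1.05 in AZD1480), with 4 of 4 AZD1480 arrays below all vehicle arrays (two-sided exact permutation p = 0.0286, the smallest possible). Without AZD1480 replicate 1 the difference was -0.82. This does not decide the hypothesis, since it came from the same list means and the feedback genes went both ways (18 lower, 13 higher), so that their mean does not measure how far STAT3-driven genes responded.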
